A study of Brassica napus with 12 samples.

How the data were processed

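ChIP-seq of H3K4me3 and H3K27me3 was compared in seedling, flower bud and silique of the *Brassica napus* hybrid HZ62, with 2 libraries per mark and tissue (12 in all). Per the labels' protocols, plants grew under 16 h light and 8 h dark at 22 and 18 °C, tissue was cross-linked with 1% formaldehyde, about 1 g was used per library, and chromatin was sonicated to 200 to 600 bp. Seedlings were 2 weeks old, buds were under 2 mm and siliques 3 to 5 cm long, per the labels. The titles call the seedling libraries leaf while the tissue field says seedling, and the second name is used here. Per the submitters' processing notes, BWA, SAMtools, GATK and MACS2 were used. The genome build is not named in the sources used here. The files name its sequences by assembly identifiers that end in a number, and that number is used here.

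Each deposited file is the peak list of 1 library, called separately and not on pooled libraries. Per the file headers, narrow peaks were called with MACS 2.2.7.1 on paired-end fragments at a q cutoff of 1e-05, with 1 fragment kept per duplicate position. Per the file headers, all 12 lists were called against the same merged control. The pileup column is a signal, the fragment coverage at the peak summit, as deposited by the authors. The p-value and q-value columns are on a −log10 scale, per the file headers. Fold enrichment is the authors' own ratio of summit pileup to the local control, given per peak, and was used to describe, rank and filter peaks within a list. Fragments per library after filtering ran from 2654588 to 14339594. The absence of a peak shows that none was called at that depth.

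Peaks of the 6 libraries of a mark were merged where they overlapped by 1 bp or more, and a library had a merged region if any of its peaks overlapped it. A region was in a tissue if both libraries had it, absent if neither did, and restricted to a tissue if both of its libraries and none of the other 4 had it. Libraries were compared by the base-pair Jaccard index. Marks were compared with a two-sided exact permutation test over 6 against 6 libraries (924 arrangements), and tissues with an exact permutation over the 15 ways to part 6 libraries into pairs. Overlap of the marks was tested on bases present in both libraries of a tissue with 1000 circular shifts of H3K27me3 within sequences. Directions of change were compared with Fisher's exact test and an odds ratio with a 95% interval, adding 0.5 to each cell where a cell was 0. P-values were adjusted by the Benjamini-Hochberg method within each family of tests.

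The groups, the tests, the alternatives and the rule for naming regions were fixed before the data were examined. By that rule the text names, per mark and pair of tissues, the 3 regions each way with the highest lower fold of the 2 libraries, the 3 widest regions in all 6 libraries of a mark, and per pair of tissues the 3 widest overlaps with opposite change. The relations with depth, the counts of regions in one tissue and not in another, the H3K27me3 shares at H3K4me3 regions that differ between tissues, the mapped stretch, the pileup requirement and the −log10 q of 10 were chosen after the data were seen. The pileup requirement counts a change only if the pileup, scaled by fragments, reaches the median pileup of each list the region is absent from. Median pileup of H3K27me3 lists did not rise in step with fragments, so for this mark the requirement asked more of regions from deeper lists. Other alternatives were an equal number of peaks per list (the 43010 strongest for H3K4me3 and 13579 for H3K27me3 by −log10 q), coverage of 50% of the merged region, permutation within tissues, a Jaccard index of regions, random placement, and leaving out each library in turn. With a library left out, its tissue was judged on the remaining library alone, so counts of regions that differ between tissues rise under this looser rule.

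Of the sequences, 19 are numbered in an order that was matched to chromosomes A1 to A10 and C1 to C9 by length: their extents in the peak lists correlated with chromosome extents of the Da-Ae assembly (Pearson r = 0.994, 0.992 without the 2 farthest, Spearman rho = 0.991, permutation p = 1e-05 each, the smallest that 100000 permutations give). No coordinate of that assembly is used here. Peaks on other sequences were at most 0.109% of a list. The gene lists planned, 10 in number, and the count of marked genes per library were not run, because no annotation of the files' build was used here. On simulated lists with 47514 regions, 100% of 200 regions planted per tissue and mark were recovered as restricted, and 20 null shifts gave a mean overlap ratio of 1.004 with p under 0.05 in 1 of them. The planted regions lay apart from others, in both libraries of a tissue, with equal strength and no difference in depth. Their recovery thus checked the counting alone, and not the effects of depth or weak peaks. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.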

Results

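The data were 12 peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HZ62, a hybrid of *Brassica napus*. This crop, oilseed rape, carries an A and a C subgenome inherited from its diploid ancestors. Antibodies against H3K4me3, a histone mark found at the starts of transcribed genes, and H3K27me3, a mark laid down by Polycomb proteins at silent developmental genes, were used on seedlings, flower buds and siliques (seed pods). Each of the 6 combinations of mark and tissue had 2 libraries. The design text also names the parents of the hybrid, which are not analysed here. The H3K4me3 libraries held 8609548 and 10914885 fragments in seedling, 9707589 and 10195899 in flower bud, and 14339594 and 11209471 in silique. The H3K27me3 libraries held 3647059 and 3479885 fragments in seedling, 11513204 and 10929797 in flower bud, and 7441109 and 2654588 in silique. Nothing in the labels says that the libraries of a group came from separate plants. P-values of tests over libraries thus measure only the spread between these libraries, which may be technical. Those from circular shifts measure placement along the sequences, and those of Fisher's and binomial tests count regions. Neither kind measures spread between libraries. Positions are given on the numbered sequences of the files, 1-based, on a genome build that the files identify only by the names of its sequences. No gene annotation of that build was used here, so regions are named by position.

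The first comparison asked how the 2 marks were laid out along the genome. H3K4me3 formed many narrow peaks, and H3K27me3 formed fewer, with a tail of very wide ones. H3K4me3 lists held 45039 ± 2499 peaks and H3K27me3 lists 22068 ± 4626 (SD, n = 6 libraries each). The widest H3K4me3 peak of a library spanned 3610 to 4380 bp, and no H3K4me3 list had a peak of 5 kb or wider. Each H3K27me3 list had between 37 and 871 such peaks, and the widest spanned 8693 to 22570 bp. The difference in peak number gave p = 0.00216 in a two-sided exact permutation test, the smallest that the 924 arrangements allow (adjusted p = 0.00433 over 4 comparisons of the marks).

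Median peak widths were 730 ± 76.8 bp for H3K4me3 and 824 ± 191.99 bp for H3K27me3 (SD, n = 6 each). This difference was within the spread between libraries (-93.3 bp, exact permutation p = 0.316, adjusted p = 0.316), and was -36.1 bp without flower bud H3K27me3 replicate 2. It passed under other settings, at -493 bp with an equal number of peaks per list (exact permutation p = 0.0216) and at -224.5 bp with −log10 q of 10 or more (exact permutation p = 0.0152). Peaks covered 35.7 ± 2.57 Mb for H3K4me3 and 26.5 ± 10.6 Mb for H3K27me3, which also did not pass the test (n = 6 each, exact permutation p = 0.0909, adjusted p = 0.121). The difference in covered length passed with an equal number of peaks per list, at 13.6 Mb (exact permutation p = 0.00216). Without flower bud H3K27me3 replicate 2 it was 11.96 Mb with an exact permutation p of 0.0108. Across the 6 H3K27me3 libraries, covered length rose with the number of fragments (Pearson r = 0.963, exact permutation p = 0.00417, adjusted p = 0.0167; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted p = 0.0333; 4 relations computed). Pearson r was 0.942 without the flower bud libraries, the 2 farthest from the median depth. Peak number of H3K27me3 also rose with fragments (Spearman rho = 1, exact permutation p = 0.00278, adjusted p = 0.0111). Its Pearson r was 0.792 (exact permutation p = 0.0292, adjusted p = 0.0583), and 0.695 without the flower bud libraries. For H3K4me3 peak number Pearson r was -0.408 (exact permutation p = 0.440) and Spearman rho -0.371 (exact permutation p = 0.497). Across the 6 H3K4me3 libraries, covered length had a Pearson r of 0.865 with the number of fragments (exact permutation p = 0.0458, adjusted p = 0.0611) and a Spearman rho of 0.429 (exact permutation p = 0.419, adjusted p = 0.497). That relation rested on seedling replicate 1 and silique replicate 1, since r was -0.0324 without them.

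**Figure D1:**
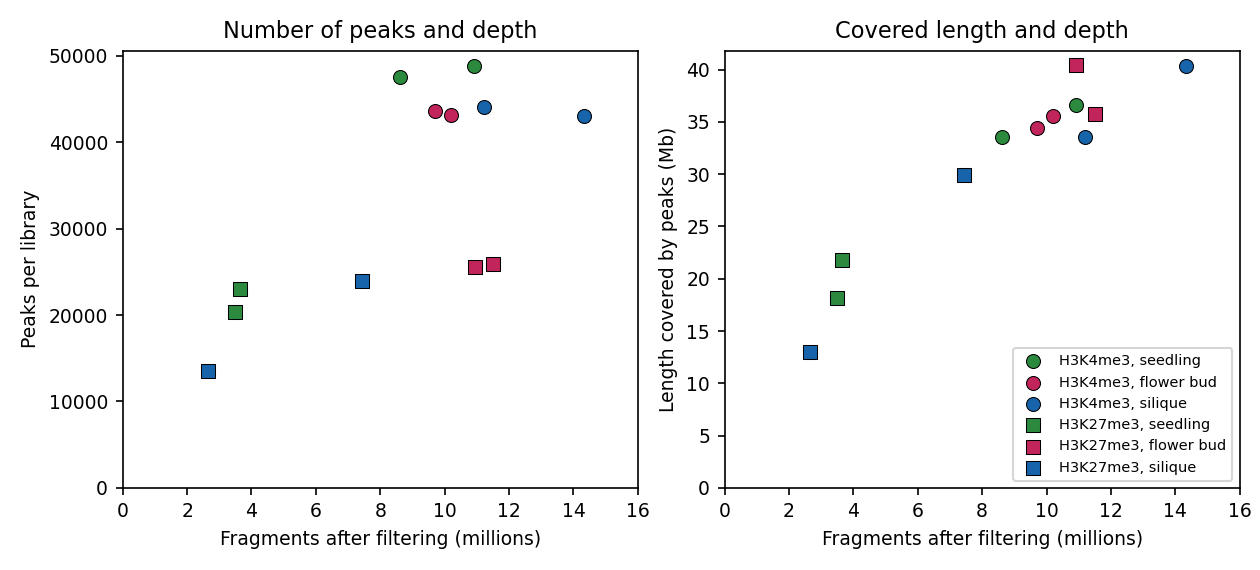
Peaks per library (left) and length covered by peaks in Mb (right) against fragments after filtering, with 1 point per library, circles for H3K4me3 and squares for H3K27me3, coloured by tissue. The H3K27me3 points climb with depth, from 13.0 Mb at 2654588 fragments to 40.4 Mb at 10929797, while H3K4me3 lists stay between 43010 and 48825 peaks.

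The widest regions present in all 6 H3K27me3 libraries lay on sequence 3 from 18753937 to 18776639 (22703 bp), on sequence 14 from 1844919 to 1863801 (18883 bp) and on sequence 16 from 45483638 to 45498992 (15355 bp). Fold enrichment, the authors' own value for each peak, reached 90.9566 in flower bud replicate 2 at the region of sequence 14 and was 35.3 in silique replicate 2. The widest H3K4me3 regions in all 6 libraries lay on sequence 12 from 31648586 to 31652965 (4380 bp), on sequence 11 from 3036191 to 3040333 (4143 bp) and on sequence 8 from 6063450 to 6067349 (3900 bp). At the region of sequence 11 the fold was 87.4 and 86.3 in silique, 49.3 and 50.3 in seedling, and 49.3 and 48.4 in flower bud.

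Both marks were denser on the sequences assigned to the A subgenome than on those assigned to C. H3K4me3 lists held 67.5 ± 3.55 peaks per Mb on A and 43.9 ± 2.56 on C, and H3K27me3 lists held 34.0 ± 6.69 on A and 21.004 ± 4.65 on C (SD, n = 6 libraries each). The density was higher on A in 12 of 12 libraries. The C subgenome held 53.3 ± 0.215% of the length covered by H3K4me3 and 51.2 ± 0.808% of that covered by H3K27me3 (SD, n = 6 each). This difference gave an exact permutation p of 0.00216, the smallest possible (adjusted p = 0.00433). The assignment rests on the order and extent of the sequences and not on their names.

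The second comparison asked whether tissues differed by more than libraries of one tissue did. For H3K4me3 every value within a tissue lay above every value between tissues: the base-pair Jaccard index, the shared length over the joint length, ran from 0.797 to 0.870 between libraries of one tissue and from 0.651 to 0.769 between tissues. For H3K27me3 the ranges overlapped, with 0.427 to 0.800 within a tissue and 0.316 to 0.691 between tissues. The lowest value within a tissue was that of the silique libraries, which differed most in depth. The mean within tissues exceeded that between tissues by 0.124 for H3K4me3 (0.840 against 0.717) and by 0.130 for H3K27me3 (0.627 against 0.497). Of the 15 ways to part 6 libraries into pairs, the grouping by tissue gave the highest difference for each mark, so that each exact permutation p was 0.0667, the smallest this design can give. The next highest was 0.0618 for H3K4me3 and 0.124 for H3K27me3. The seedling libraries carry library numbers 53 to 66 and all others belong to a later series of numbers, so seedling and library series cannot be told apart. Fragment sizes differed as well. For H3K4me3 they were 236 and 246 bp in seedling, 304 and 310 bp in flower bud, and 332 and 248 bp in silique. For H3K27me3 they were 226 and 228 bp, 279 and 294 bp, and 272 and 283 bp in the same order. The effect of fragment size on these comparisons was not tested. Within the later series, the H3K4me3 index was 0.870 in flower bud and 0.797 in silique, against 0.734 to 0.769 between these tissues, and the H3K27me3 index was 0.800 and 0.427, against 0.316 to 0.691.

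Most H3K4me3 regions were shared by the tissues, and seedlings had the most regions of their own. Of 51928 merged H3K4me3 regions, 37889 (73.0%) had a peak in all 6 libraries, and 2304 had a peak in 1 library only. There were 3244 regions present in both seedling libraries and absent from the other 4, 592 restricted in this way to flower bud and 687 to silique. The 12 pairs of libraries from different tissues shared at most 63 such regions, with a median of 24. The restricted regions were narrow, with median widths of 518 bp in seedling, 628 bp in flower bud and 639 bp in silique, against 944 bp for regions in all 6 libraries. These are widths of merged regions, which join peaks of more libraries where a region is shared, so part of this difference may be built in. Restricted regions were also weak: in seedling replicate 1 their median fold was 7.44, against 18.2 for regions in all 6 libraries. With an equal number of peaks taken from each list the counts were 1669, 895 and 936. Requiring a pileup, scaled for depth, that reached the median of every list without the region left 57, 16 and 8, a setting chosen after the data were seen.

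**Figure D2:**
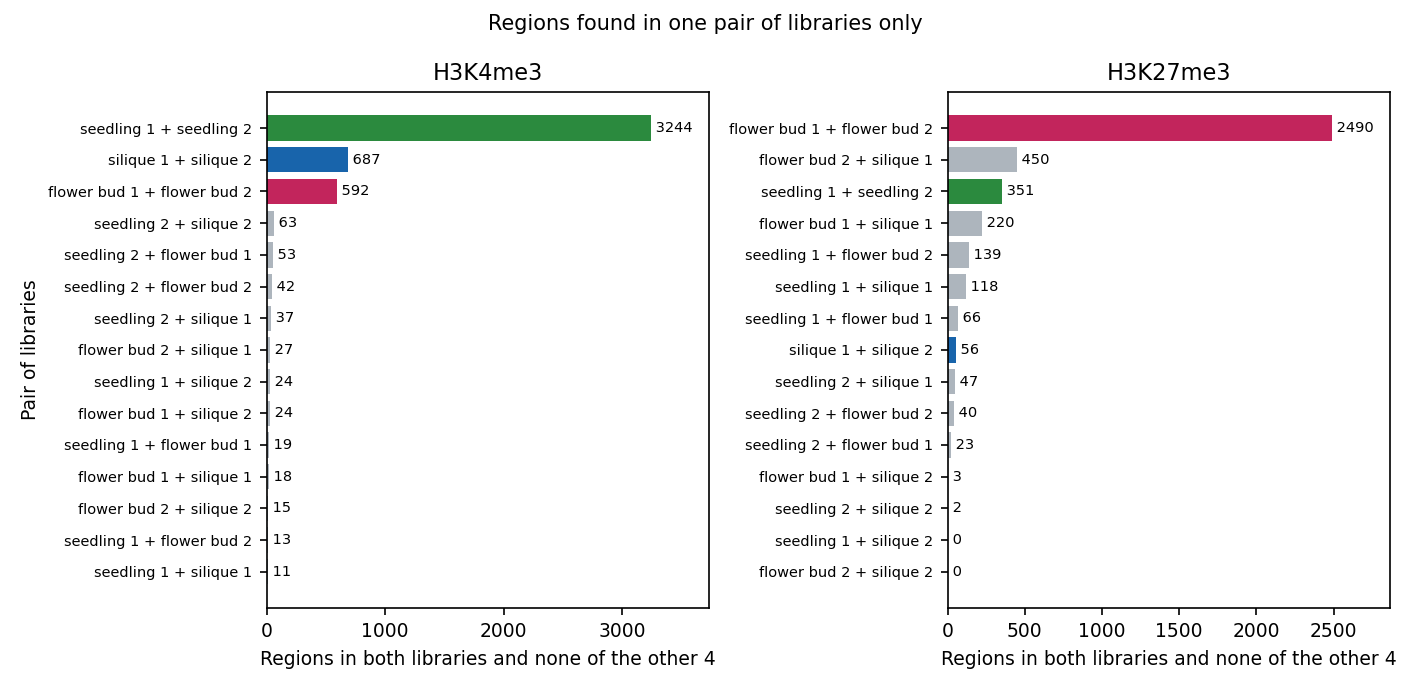
Number of merged regions (horizontal axis) with a peak in both libraries of a pair and in none of the other 4, for the 15 pairs of libraries of each mark (vertical axis); coloured bars are pairs from 1 tissue and grey bars are mixed pairs. For H3K4me3 the pairs of 1 tissue have 592 to 3244 regions and mixed pairs at most 63, while for H3K27me3 a mixed pair reaches 450, above seedling at 351 and silique at 56.

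Between seedling and flower bud, 4839 H3K4me3 regions were present in both seedling libraries and neither flower bud library, and 1392 the other way. Under the pileup requirement the counts were 150 and 84. With an equal number of peaks per list they were 2751 and 2808, with no excess of seedling. Cutting the longer seedling lists to equal length may itself remove an excess, so that setting does not decide the direction. The strongest in seedling and not in flower bud lay on sequence 14 from 2071910 to 2073647, with folds of 50.4 and 57.0 in the 2 seedling libraries, on sequence 3 from 15007506 to 15008782, with 48.5 and 46.9, and on sequence 1 from 29913640 to 29914758, with 51.3 and 43.6. All of these also had peaks in both silique libraries, with folds of 5.83 to 24.3. The strongest in flower bud and not in seedling lay on sequence 10 from 31635 to 33278, with folds of 55.2 and 56.1, on sequence 9 from 44472917 to 44474826, with 55.9 and 50.95, and on sequence 15 from 44528 to 46041, with 52.9 and 40.3. These 3 were present in both silique libraries as well.

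Between seedling and silique, 4798 H3K4me3 regions were in seedling and not in silique, and 1505 the other way. Under the pileup requirement the counts were 170 and 83. With an equal number of peaks they were 2733 and 2814, again with no excess of seedling and with the limit that its longer lists were cut. The strongest in seedling lay on sequence 14 from 16337857 to 16339178, with folds of 56.5 and 45.5, on sequence 2 from 33173997 to 33175410, with 42.6 and 41.7, and on sequence 11 from 2289360 to 2291634, with 40.1 and 39.7. The regions of sequences 2 and 11 had no peak in flower bud either. The strongest in silique were the region of sequence 9 from 44472917, with folds of 46.2 and 46.4, another on sequence 2 from 10106435 to 10108587, with 45.8 and 40.0, and another on sequence 9 from 29245552 to 29247661, with 34.2 and 39.5.

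Between flower bud and silique, 1881 H3K4me3 regions were in flower bud and not in silique and 2004 the other way. Under the pileup requirement the counts were 65 and 29. Leaving out flower bud replicate 2 (2410 and 2392) or silique replicate 2 (2418 and 2398) also turned the direction. The strongest in flower bud lay on sequence 13 from 38926646 to 38928104, with folds of 54.4 and 57.3, on sequence 15 from 24022097 to 24023506, with 55.9 and 47.5, and on sequence 6 from 20515221 to 20516828, with 42.2 and 39.2. All of these had peaks in both seedling libraries. The strongest in silique lay on sequence 6 from 25128359 to 25129798, with folds of 33.8 and 40.3, on sequence 17 from 43707041 to 43708304, with 31.6 and 35.5, and on sequence 9 from 18582055 to 18583413, with 36.5 and 31.0. The first and second of these were in silique alone.

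H3K27me3 regions were shared less widely, and flower bud had the most of its own. Of 29471 merged H3K27me3 regions, 9625 (32.7%) had a peak in all 6 libraries and 4867 (16.5%) in 1 library only. Restricted regions numbered 2490 in flower bud, 351 in seedling and 56 in silique. Pairs of libraries from different tissues shared up to 450 such regions, with a median of 43.5, so the seedling and silique counts did not stand above the spread between libraries. Restricted regions had median widths of 650 bp in flower bud, 562 bp in seedling and 790 bp in silique, against 2284 bp for regions in all 6 libraries. Widths are again of merged regions, so part of this difference may be built in. The flower bud libraries were also the deepest of this mark: equal numbers of peaks gave 688 for flower bud, 439 for seedling and 265 for silique, and the depth-scaled requirement on pileup left 11, 24 and 9. That requirement asked more of the deeper lists, so the fall in flower bud may be partly built in. Leaving out a single library loosens the rule, since its tissue is then judged on 1 library, and these counts rose. Flower bud rose to 5253 without silique replicate 1 and to 4318 and 3946 without its own replicates 1 and 2. Seedling rose to 708 and 1174, and silique to 86 and 1127, each without its own replicates 1 and 2.

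Named H3K27me3 regions included some with high folds in 2 tissues and no peak in the third. A region of 6154 bp on sequence 4 from 21118870 to 21125023 had folds of 48.6 and 53.4 in flower bud and 46.5 and 25.8 in silique, and no peak in seedling. Flower bud was also above seedling on sequence 15 from 5246971 to 5249425, with folds of 42.4 and 46.7, and on sequence 9 from 41903945 to 41907295, with 36.1 and 45.3, where seedling had no peak. Silique had peaks where seedling had none on sequence 1 from 1144968 to 1151054, with folds of 49.3 and 30.7, and on sequence 11 from 13354640 to 13356846, with 28.0 and 27.6. Seedling alone had peaks at 3 places close together on sequence 13, from 26430121 to 26431060, with folds of 23.2 and 29.1, from 26449792 to 26450445, with 30.2 and 30.4, and from 26450968 to 26452234, with 23.5 and 24.8.

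Against silique, flower bud H3K27me3 was present and silique had no peak on sequence 15 from 2670483 to 2673055, with folds of 32.0 and 37.2, on sequence 1 from 5625391 to 5634009, a region of 8619 bp with 23.1 and 26.9, and on sequence 19 from 54996271 to 54998058, with 21.9 and 23.0. The first and second of these were also present in both seedling libraries. Silique had peaks and flower bud none on sequence 9 from 26262140 to 26264627, with folds of 19.1 and 14.9, on sequence 13 from 26672010 to 26672929, with 19.4 and 13.4, and on sequence 9 from 38010235 to 38011793, with 21.5 and 13.2. Over all regions, 5780 were in flower bud and not in seedling and 467 the other way, 3606 were in flower bud and not in silique and 78 the other way, and 978 were in seedling and not in silique and 630 the other way. With an equal number of peaks the counts in the same order were 2010 and 671, 1224 and 440, and 830 and 1247, and under the pileup requirement 253 and 169, 21 and 32, and 55 and 178. The order of seedling and silique thus turned under both, and that of flower bud and silique under the pileup requirement. Neither is a measured reversal. The equal number, 13579, was the length of the silique replicate 2 list, and the other H3K27me3 lists were cut to it. The pileup requirement asked more of deeper lists. Leaving out single H3K27me3 libraries raised 5 of these counts by over 1.5 times, under the looser rule of 1 library for the tissue concerned. Those in seedling and not in flower bud became 874 and 1417 without seedling replicates 1 and 2, and those in seedling and not in silique 1573 and 2463 without the same libraries and 4581 without silique replicate 1. Those in flower bud and not in silique became 5714 without flower bud replicate 1 and 11665 without silique replicate 1. Those in silique became 1182 without seedling replicate 1 and 5107 without silique replicate 2 where seedling had none, and 122 without flower bud replicate 2 and 1414 without silique replicate 2 where flower bud had none.

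The third comparison asked how far the 2 marks lay on the same bases in one tissue. They overlapped less than chance placement gave in all 3 tissues. Bases marked in both libraries by both marks came to 0.362 Mb in seedling against 0.626 ± 0.0294 Mb expected from circular shifts, 0.795 against 1.35 ± 0.0565 Mb in flower bud, and 0.327 against 0.517 ± 0.0261 Mb in silique (SD over 1000 shifts). The ratios were 0.578 in seedling (0.529 to 0.632 against the central 95% of the shifts), 0.589 in flower bud (0.547 to 0.642) and 0.631 in silique (0.573 to 0.699). Each gave a two-sided permutation p of 0.002, the smallest that 1000 shifts allow (adjusted p = 0.002 over 3 tissues). Bases with both marks were 2.29%, 2.35% and 2.55% of the H3K27me3 length in seedling, flower bud and silique.

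The fourth comparison asked whether both marks changed at the same regions from tissue to tissue. Where an H3K4me3 region and an overlapping H3K27me3 region both differed between 2 tissues, they mostly differed in opposite directions. Overlap was judged between merged regions, which peaks of another tissue could widen. From seedling to flower bud, 525 of 543 overlapping pairs of regions (96.7%) changed in opposite directions, 498 of them losing H3K4me3 and gaining H3K27me3. From seedling to silique it was 205 of 217 (94.5%), and from flower bud to silique 136 of 160 (85.0%), of which 126 gained H3K4me3 and lost H3K27me3. With no association between the marks, the gains and losses of each mark among these same overlapping pairs gave 87.6%, 54.7% and 75.2%. These splits depended on the setting: the loss of H3K4me3 with gain of H3K27me3 and the reverse numbered 498 and 27 from seedling to flower bud, 229 and 57 with an equal number of peaks, and 16 and 9 under the pileup requirement. From flower bud to silique they numbered 10 and 126, 25 and 80, and 3 and 1. The odds ratio of a change in the same direction was 0.00238 from seedling to flower bud (95% interval 0.00052 to 0.0109, Fisher's exact test adjusted p = 4.62e-32), 0.00117 from seedling to silique (0.000148 to 0.00927, Fisher's exact test adjusted p = 4.1e-43) and 0.00922 from flower bud to silique (0.000523 to 0.163, Fisher's exact test adjusted p = 5.77e-08). Regions are not independent replicates, so these intervals and p-values cover counting error alone. Leaving out 1 library moved 6 of 8 odds ratios of each seedling comparison and 1 of 8 from flower bud to silique by over 1.5 times, all toward 1. From seedling to flower bud the ratio was 0.0087 and 0.00632 without seedling H3K27me3 replicates 1 and 2, 0.00436 without seedling H3K4me3 replicate 1, 0.00393 and 0.00599 without flower bud H3K4me3 replicates 1 and 2, and 0.00515 without flower bud H3K27me3 replicate 2. From seedling to silique it was 0.00386 and 0.00365 without seedling H3K27me3 replicates 1 and 2, 0.00243 and 0.00241 without seedling H3K4me3 replicates 1 and 2, and 0.0035 and 0.00686 without silique H3K27me3 replicates 1 and 2. From flower bud to silique it was 0.0306 without silique H3K27me3 replicate 2. Opposite pairs from seedling to silique numbered 464 of 492 without silique H3K27me3 replicate 2 and 289 of 363 (79.6%) without silique H3K27me3 replicate 1, and 305 of 388 from flower bud to silique without silique H3K27me3 replicate 1. The lowest share of opposite changes with a library left out was 78.6% of 388 pairs, from flower bud to silique without silique H3K27me3 replicate 1, against 74.3% with no association. Other settings also moved the odds ratios by over 1.5 times, from seedling to flower bud to 0.0103 with 50% coverage of the region, from seedling to silique to 0.00304 with an equal number of peaks, and from flower bud to silique to 0.00183 with an equal number, 0.00354 with 50% coverage and 0.0476 under the pileup requirement.

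The widest overlaps with opposite change were found between seedling and silique. On sequence 8 from 18524374 to 18526696 (2323 bp), silique had H3K4me3 with folds of 31.2 and 25.3, and seedling had H3K27me3 with folds of 15.5 and 13.9. The same arrangement stood on sequence 15 from 17931563 to 17933758, with H3K4me3 folds of 24.97 and 20.04 and H3K27me3 folds of 15.04 and 14.8, and on sequence 13 from 58856992 to 58859179, with 20.5 and 18.1 and with 16.6 and 13.7. Seedling had H3K4me3 and flower bud H3K27me3 on sequence 7 from 28617824 to 28619868, on sequence 8 from 20857046 to 20859054 and on sequence 16 from 48532407 to 48534374, overlaps of 2045, 2009 and 1968 bp. Silique had H3K4me3 and flower bud H3K27me3 on sequence 9 from 4185055 to 4186882. The reverse held on sequence 17 from 22461148 to 22462627 and on sequence 7 from 10622810 to 10624226.

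One place was named under both marks. On sequence 9, H3K27me3 covered 29244899 to 29248062 with folds of 30.8 and 27.02 in seedling and 8.69 and 9.97 in flower bud, and had no peak in silique. Inside it, H3K4me3 covered 29245552 to 29247661 with folds of 18.4 and 16.4 in flower bud and 34.2 and 39.5 in silique, and had no peak in seedling. Flower bud had peaks of both marks there. Libraries were made from bulk tissue, so this does not show both marks in the same cells. Both seedling libraries, and no other, had an H3K4me3 peak just left of it, from 29243455 to 29244072 in replicate 1, with folds of 9.53 and 7.92. An H3K4me3 peak farther left was present in all 6 libraries and an H3K27me3 peak to its right in all 6 of that mark.

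**Figure D3:**
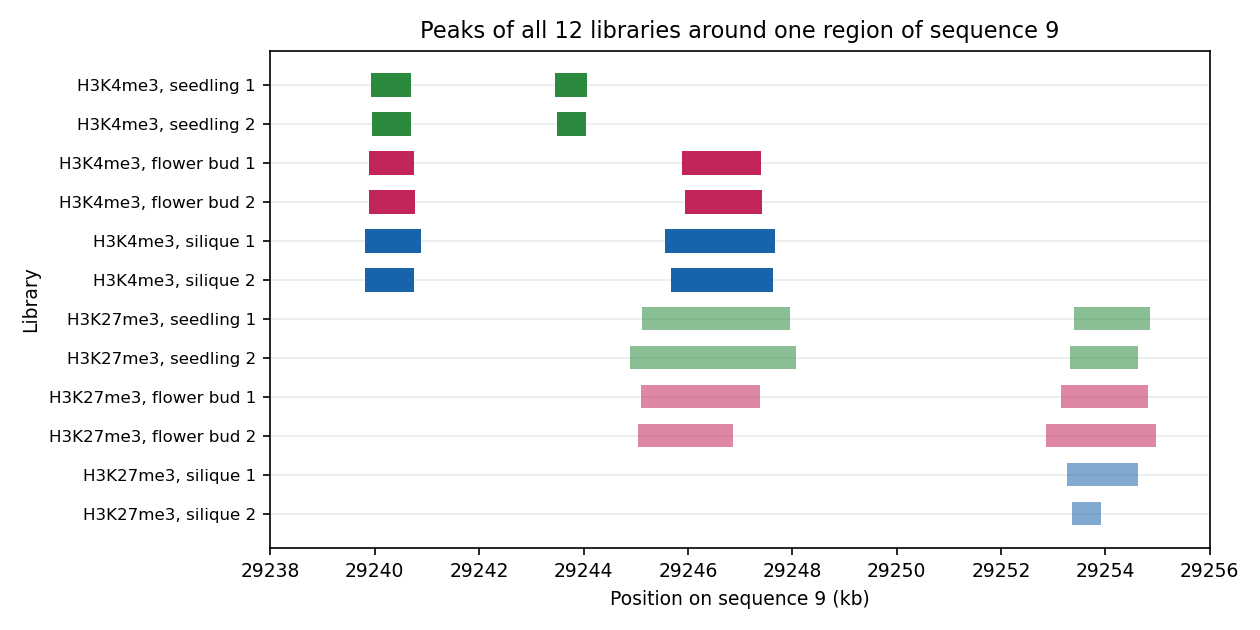
Peaks of the 12 libraries along a stretch of sequence 9 (horizontal axis, position in kb), 1 row per library, solid bars for H3K4me3 and pale bars for H3K27me3, coloured by tissue. At 29244899 to 29248062 H3K27me3 peaks stand in seedling and flower bud and H3K4me3 peaks in flower bud and silique; the peak from 29243455 to 29244072 is of seedling H3K4me3.

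The last comparison, added after the data were seen, asked what H3K27me3 did at H3K4me3 regions that one tissue had and another lacked. Such regions overlapped H3K27me3 regions far more often than H3K4me3 regions common to both tissues did. A region counted as having H3K27me3 in a tissue if it overlapped a merged H3K27me3 region that both libraries of the tissue had. Peaks of other tissues could widen that merged region, so the tissue's own peak need not lie on the H3K4me3 region. Of 1392 H3K4me3 regions in flower bud and not in seedling, 20.9% had H3K27me3 in seedling (exact 95% interval 18.8 to 23.1%), against 1.38% (1.27 to 1.5%) of 39775 regions in both. For the 1505 in silique and not in seedling the share with H3K27me3 in seedling was 21.6%, against 1.45%. For H3K27me3 in flower bud the shares were 22.4% of 4839 regions in seedling and not in flower bud, against 2.67%, and 24.5% of 2004 in silique and not in flower bud, against 2.72%. For H3K27me3 in silique they were 11.4% of 4798 regions in seedling and not in silique, against 1.3%, and 12.2% of 1881 in flower bud and not in silique, against 1.3%. Odds ratios ran from 9.72 to 18.9, and the highest adjusted p of the 6 was 4.72e-126 in Fisher's exact test, again over regions that are not independent.

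The share was also raised in the tissue that had the H3K4me3. It was counted by the same rule of merged regions. These shares thus do not show both marks on the same bases or in the same cells. Of the same 1392 regions in flower bud and not in seedling, 21.6% had H3K27me3 in flower bud itself, against 2.67% of the regions in both tissues. The shares in the tissue with H3K4me3 were 12.1% for silique and not seedling, 9.46% for seedling and not flower bud, 9.78% for silique and not flower bud, 8.69% for seedling and not silique, and 16.1% for flower bud and not silique. Under the depth-scaled requirement on pileup, 23.5 to 59.5% of the remaining H3K4me3 regions had H3K27me3 in the tissue that lacked H3K4me3, and 7.65 to 46.4% had it in the tissue with H3K4me3. Other settings gave lower shares. With an equal number of peaks they were 10.9 to 15.95% in the tissue that lacked H3K4me3, against 0.752 to 1.48% of regions in both, and 4.76 to 9.97% in the tissue with it. With 50% coverage they were 5.31 to 21.5%, against 0.393 to 2.12%, and 2.31 to 14.2% in the tissue with H3K4me3, where silique and not seedling fell from 12.1 to 2.31%.

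**Figure D4:**
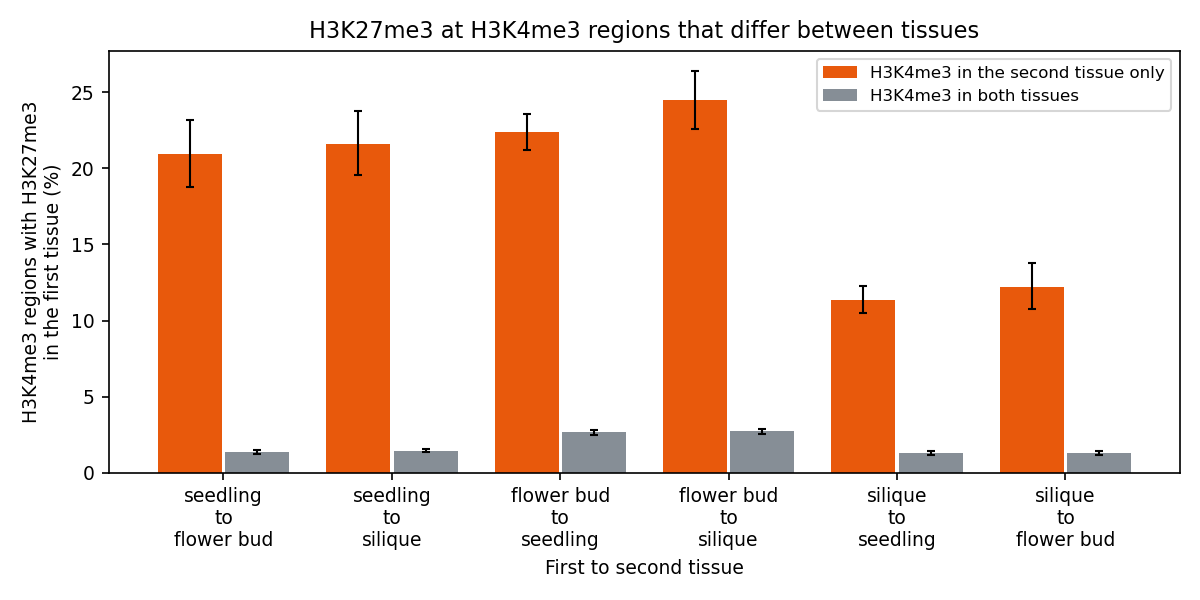
Percentage of H3K4me3 regions that overlapped a merged H3K27me3 region present in the first tissue (vertical axis), for each order of tissues (horizontal axis). Regions had H3K4me3 in the second tissue only (orange) or in both (grey). Error bars are exact 95% binomial intervals over regions. Orange bars stand at 11.4 to 24.5% and grey bars at 1.3 to 2.72%.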

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

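The tests of seedling depth and of the library series were chosen after the results were seen, and the pileup requirement used by the others was itself added after the data were examined. The contrast between the marks differed between tissues in 3 cases, none of them tested. In covered length, H3K4me3 exceeded H3K27me3 by 15.1 Mb in seedling, while in flower bud the difference was -3.10 Mb, a gap of 18.2 Mb in which both libraries of each tissue took opposite sides. Silique, with a difference of 15.5 Mb, stood in the same way against flower bud (flower bud less silique, -18.6 Mb). Peak number fell from seedling to flower bud for H3K4me3 and rose for H3K27me3, so that the excess of H3K4me3 peaks was 26532.5 in seedling and 17618.5 in flower bud, a gap of 8914. Depth cannot be told apart from tissue in these cases. H3K27me3 libraries had 3647059 and 3479885 fragments in seedling, 11513204 and 10929797 in flower bud, and 7441109 and 2654588 in silique. Both covered length and peak number of this mark rose with fragments. No group had enough libraries for a test of single libraries that stand apart.

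Seedling had 3244 restricted H3K4me3 regions against 687 and 592 in the other tissues, and 1669 against 936 and 895 with equal numbers of peaks. At that setting seedling had no excess over either tissue taken singly (2751 and 2808 against flower bud, 2733 and 2814 against silique). Flower bud and silique lists were also more alike (Jaccard index 0.734 to 0.769) than seedling lists were to either (0.651 to 0.719). The restricted count at equal numbers thus does not by itself show more H3K4me3 regions in seedling. Greater depth than silique was argued against, the deeper seedling library having 0.974 times the fragments of the shallower silique library, while against flower bud the fragments overlapped (8609548 and 10914885 against 9707589 and 10195899) and did not decide. Among regions that met the pileup requirement, scaled by fragments, seedling had 57 and flower bud, the next tissue, 16. The ratio was 3.56 (95% counting interval 2.05 to 6.2, over regions that are not independent). This argued against depth relative to flower bud and weak peaks near the calling threshold for these 57 regions alone. The 3244 as a whole were weak, with a median fold of 7.44 in seedling replicate 1 against 18.2 for regions in all 6 libraries. For the rest of them weak peaks and depth relative to flower bud stay open. The library series stays open and cannot be told apart from the tissue, because 0 tissues had libraries in both series. Fragment size, 236 and 246 bp in seedling H3K4me3 libraries, 304 and 310 bp in flower bud and 332 and 248 bp in silique, was not tested either. A biological difference of seedlings from the other tissues stays open as well, untested.

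Flower bud had 2490 restricted H3K27me3 regions against 351 and 56. Depth may account for part or all of this excess: flower bud libraries had 11513204 and 10929797 fragments, against 2654588 to 7441109 elsewhere. Under the pileup requirement flower bud had 11 regions and seedling 24, a ratio of 0.458 (0.225 to 0.936). That requirement asked more of deeper lists, because median pileup did not rise in step with fragments. It was 49 in flower bud replicate 1 (11513204 fragments) and 21 in seedling replicate 1 (3647059). The fall of flower bud may thus be partly built in, and this ratio does not decide on depth. With equal numbers of peaks flower bud still had the most, 688 against 439 and 265. A difference between the tissues stays open, untested by these lists.

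The marks changed in opposite directions at 85.0 to 96.7% of the overlapping pairs of regions, where no association gave 54.7 to 87.6%. The prediction for depth was that the pattern would be gone under the pileup requirement. It was not, with 58 of the 58 remaining pairs opposite, against 53.3% with no association (odds ratio 0.000304, 95% interval 5.83e-06 to 0.0159). This does not decide on depth. The odds ratio already allows for the numbers of gains and losses, which depth can set. The requirement also kept strong regions alone, and the marks avoided the same bases within a tissue. Few pairs changing in the same direction could thus remain. The 58 were counted over 3 pairs of tissues, so the same place can count again. The library series was not separated from this pattern in the seedling comparisons, but within the later series 136 of 160 pairs from flower bud to silique were opposite (Fisher's exact p = 5.77e-08), and 93.75% of 112 with equal numbers of peaks (Fisher's exact p = 5.57e-19), over regions that are not independent. Under the requirement 4 pairs were left there, too few for the test to pass. A switch of the marks between tissues is a hypothesis.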

How the results depend on the processing

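The pileup requirement and the −log10 q of 10 were added after the data were seen. No tested difference or ratio changed direction, but several orders of counts did. With an equal number of peaks, H3K27me3 regions in seedling and not in silique against the reverse turned from 978 and 630 to 830 and 1247. H3K4me3 regions of seedling against flower bud (2751 and 2808) and silique (2733 and 2814) came out near equal there, with the order turned by a small margin. Cutting longer lists to equal length may itself produce such turns for either mark, so they are not read as measured reversals. Under the pileup requirement H3K27me3 regions in seedling and not in silique against the reverse became 55 and 178. Flower bud and silique turned from 1881 and 2004 to 65 and 29 for H3K4me3 and from 3606 and 78 to 21 and 32 for H3K27me3. Restricted H3K27me3 regions of flower bud and seedling turned from 2490 and 351 to 11 and 24. Restricted H3K4me3 regions of flower bud and silique turned from 592 and 687 to 16 and 8. That requirement asked more of deeper H3K27me3 lists, so its H3K27me3 turns may be partly built in. Leaving out a library turned flower bud against silique for H3K4me3 (2410 and 2392, and 2418 and 2398, without replicate 2 of either; restricted regions 781 and 769, and 793 and 764, without flower bud replicates 1 and 2). Without silique replicate 2, H3K27me3 turned for seedling against silique (991 and 5107, with restricted regions 351 and 1127). With a library left out its tissue is judged on 1 library, so these turns may come from that looser rule. Peak number, C subgenome share, the overlap ratio of the marks and the H3K27me3 shares at changed H3K4me3 regions stayed on their side of 0.05 under each alternative run on them, while the Jaccard comparisons cannot pass it by design. The planned −log10 q of 5 removed 0 peaks, being the authors' own cutoff, and is void; a value of 10 removed 1.16 to 22.5% of a list. With an equal number of peaks, the median width differed by -493 bp (exact permutation p = 0.0216) and covered length by 13.6 Mb (exact permutation p = 0.00216), and restricted H3K4me3 regions were 1669 in seedling and 895 in flower bud, and H3K27me3 regions 688 in flower bud and 265 in silique. With −log10 q of 10 or more, the median width differed by -224.5 bp (exact permutation p = 0.0152) and silique had 29 restricted H3K27me3 regions. With 50% coverage, 3091 H3K27me3 regions were in all 6 libraries and 4406 were restricted to flower bud; the cause was not tested. Under the pileup requirement, which by construction keeps strong regions alone, restricted regions in seedling, flower bud and silique were 57, 16 and 8 for H3K4me3 and 24, 11 and 9 for H3K27me3, and the odds ratio of flower bud to silique was 0.0476 (Fisher's exact p = 0.25) on 4 pairs, with 0.25 the smallest p these pairs allow. Leaving out a library gave covered length differences of 6.47 to 11.96 Mb and restricted H3K27me3 regions of 351 to 1174 in seedling, 2500 to 5253 in flower bud and 58 to 1127 in silique. Of the counts of regions between 2 tissues, the equal number moved 8 of 12 by over 1.5 times and the pileup requirement 12 of 12. With 50% coverage 4 moved so, H3K4me3 regions absent from seedling from 1392 to 2403 in flower bud and from 1505 to 2513 in silique, and H3K27me3 regions of flower bud from 5780 to 10305 against seedling and from 3606 to 5627 against silique. With −log10 q of 10 or more 2 did, H3K27me3 regions absent from flower bud from 467 to 309 in seedling and from 78 to 45 in silique. No paired analysis was possible because the labels give each library its own number, with none shared between groups. Depth limits most the H3K27me3 list of silique replicate 2, with 2654588 fragments. The gene lists and the alternative around gene starts were not run.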

Other observations

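The marks shared broad territory while avoiding the same bases. Over 869 windows of 1 Mb, the length covered by H3K4me3 and by H3K27me3 had a Spearman correlation of 0.769 in seedling, 0.796 in flower bud and 0.772 in silique, across windows that are not independent replicates. H3K27me3 was missing from 38 of these windows in seedling, 21 in flower bud and 49 in silique. Of 853 windows tested, 2 held more seedling-restricted H3K27me3 regions than the genome-wide share gave in a one-sided exact binomial test adjusted over windows. These lay on sequence 1 from 23000001 to 24000000, with 7 of 42 regions (exact binomial adjusted p = 0.000536), and on sequence 2 from 27000001 to 28000000, with 6 of 51 (exact binomial adjusted p = 0.0137). For silique, 1 window passed, on sequence 9 from 10000001 to 11000000, with 3 of 30 regions (exact binomial adjusted p = 0.0229). For flower bud H3K27me3 and for H3K4me3 in each tissue, 0 windows passed; with few restricted regions per window, these tests say little of how far such regions cluster.

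A hypothesis was that H3K27me3 restricted to a tissue may lie beside lasting H3K27me3. Of 2485 flower bud regions, 21.3% lay within 5 kb of a region present in all 6 libraries, against 14.2 ± 0.913% under 1000 circular shifts, a ratio of 1.51 (permutation p = 0.002, the smallest possible). Of 350 seedling regions it was 37.4% against 13.9 ± 2.05%, a ratio of 2.69 (permutation p = 0.002, the smallest possible). The shifts keep the spacing of the shifted regions but break the broad territory that the 2 sets share along a sequence. Part of each ratio may thus come from regions that gather in the same territory. Edges of wide domains called as separate peaks were not set apart from new regions.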
